A study of Homo sapiens with 8 samples.

How the data were processed

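Mature microRNAs (miRNAs) were measured in CD71+ erythroid cells from venous blood of 8 people, on 1 array each. CD71 is the transferrin receptor, carried by nucleated erythroid precursors and reticulocytes. The labels assign 2 arrays to controls without sickle cell anaemia (SCA), 3 to untreated SCA and 3 to SCA under hydroxyurea, a ribonucleotide reductase inhibitor. Per the labels' protocols, CD45+ cells were depleted before CD71+ cells were enriched on magnetic columns, and total RNA was labelled with Cy3. The groups hold separate people, so each array was 1 biological replicate, and the number of arrays limits the precision of each value.

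The deposited scanner files hold the spot intensity in 1 colour, written by Agilent Feature Extraction 10.5.1.1 per the file headers and the submitters' processing notes. Per the file headers, the processed intensity had the local background subtracted and spatial trends removed, with no surrogate for negative values and no scaling between arrays. The headers name the human genome build hg18. Each array held 13737 features, of which 953 were controls and 12784 were spots for 2421 probes against 795 miRNAs (719 human and 76 viral), with 3 to 16 spots per probe and 1 to 6 probes per miRNA. A series table of 1 intensity per miRNA and array was also deposited, and how the authors normalized it is not given in the sources used here. Its values were set against the scanner values of the same array, over all miRNAs. Each column correlated best with its own array, with Spearman correlations of 0.978 to 0.983. The scanner signal over the table value had medians between 25.3 and 43.7 across arrays, so the table was scaled per array by factors that stay unknown. The columns ran from 0 upward on a linear scale. Their medians were 0.0896 and 0.0734 for control replicates 1 and 2, and 0.107, 0.0721 and 0.0973 for untreated replicates 1 to 3. For treated replicates 1 to 3 they were 0.0618, 0.0902 and 0.0559. The table served as an alternative source of values.

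Control features and spots marked as outliers were left out, and no spot was saturated. The processed intensity was averaged over the spots of a probe and over the probes of a miRNA. A probe was detected on an array when more than 50% of its spots were well above background, and a miRNA was detected when any of its probes was. Each array was divided by the 75th percentile of the 275 human probes detected on all 8 arrays. Values under 1 common floor of 0.0119 (log2 of -6.40) were set to it before log2 was taken. The floor was the highest over arrays of the 1st percentile of the scaled signal of detected miRNAs. Levels are therefore log2 values relative to the array's 75th percentile, and differences that touch the floor are understated. Human miRNAs detected on every array of at least 1 group were tested, which left 171 of 719 (23.8%), and 141 were detected on all 8 arrays. The others could enter through 1 group alone, which favours values that are higher in that group.

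Group differences were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided) on all 8 arrays together, with version 1.17.8 of data.table for reading and joining. All arrays shared 1 estimate of the spread, with 5 residual and 1.27 prior degrees of freedom. P values were adjusted by Benjamini-Hochberg over the 171 miRNAs of a comparison, with a threshold of 0.05. Comparisons were treated against untreated SCA, untreated SCA against control, treated SCA against control, the mean of both SCA groups against control, and an F test over the 3 groups. Values per array, such as the share of the signal taken by 1 miRNA, were compared by exact two-sided permutation tests. Where a group had no array with the miRNA detected, its values were kept at or above the common floor, as for all others.

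Lists of miRNAs were fixed before the data were examined, as were the tests, the rule for named miRNAs and most alternatives. There were 14 lists: erythroid and red cell, fetal globin, hydroxyurea candidates, let-7 family, the miR-17 to miR-92a cluster and its paralogues, myeloid, lymphoid, platelet and megakaryocyte, haematopoietic progenitor, the 14q32 cluster, p53 and DNA damage, hypoxia, GC-rich probes prone to background, and other tissues. The hydroxyurea candidates came from memory of published work and may have been chosen on these same samples, so they are not independent evidence. Lists with at least 3 tested members were tested with limma's camera (preset correlation 0.01), with an estimated correlation and with fry, adjusted over 12 lists per comparison. The value of a list is its median log2 difference minus the median of all tested miRNAs. Subtracting that median was decided after the plain medians were seen. Named miRNAs were those past the threshold whose groups did not overlap, filled up by the smallest unadjusted p to 20, 20 and 10 for the treated-untreated, untreated-control and treated-control comparisons. A fixed set of erythroid, myeloid and candidate miRNAs and the 3 members of each list with the smallest unadjusted p were also named.

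All arrays came from 1 slide and 1 scan, and the array row on the slide was the only technical batch tested. The array column on the slide also differed and was not tested. Batches of blood collection, cell enrichment, RNA extraction or labelling were not examined. Both controls lay in row 2, and each SCA group had 2 arrays in row 1 and 1 in row 2. Row was tested as a block and within rows. Other alternatives were 3 scalings (all human probes, quantile, median), normexp background correction (offset 50), the gene-level signal of Feature Extraction, the brightest probe, the series table, a floor at 0.5 of its value, no filter, a stricter filter, a trended robust prior, a fit of only the groups compared, the replicate number as a block, and leaving out each array. A soft floor, a restriction to miRNAs above the floor on all arrays and camera with an estimated correlation under each other setting were chosen after seeing the data.

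Each step of the fit was tested on simulated data for the treated-untreated comparison, in 100 data sets of 171 miRNAs with 10 changed at each fold. The share recovered was 59.8% at 1.5-fold, 86.6% at 2-fold and 98.8% at 4-fold, with 1.19 false calls among 25.7 calls per data set. Many changed miRNAs make the Benjamini-Hochberg adjustment less strict. These shares therefore do not apply to the data, where 1 miRNA passed between treated and untreated SCA. Positions are those of the probe targets, on hg18 as the scanner files give them. Host genes are named from the RefSeq annotation of GRCh38.p14, whose coordinates were not used, and 45 of the 48 named miRNAs matched a gene in it. Simulated unchanged groups sharing the untreated arrays were drawn 1000 times. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.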

Results

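Levels of 719 human miRNAs were measured in CD71+ erythroid cells on 8 one-colour arrays. The arrays fell into 3 groups of separate people: 2 controls without SCA, 3 with untreated SCA and 3 with SCA treated with hydroxyurea, a drug that slows DNA synthesis and raises fetal haemoglobin. The 75th percentile used for scaling averaged 439 ± 46.8 intensity units in controls (SD, n = 2), 450 ± 95.8 in untreated SCA (SD, n = 3) and 607 ± 143 in treated SCA (SD, n = 3). An exact two-sided permutation test of treated against untreated arrays gave p = 0.2 for it, and 3 against 3 arrays allow no value under 0.1. On average 160.5 human miRNAs were detected in controls, 170 in untreated and 189 in treated SCA. Arrays correlated with each other at 0.982 to 0.996 across the tested miRNAs, which are not independent replicates. The highest correlation was between treated replicate 2 and untreated replicate 3, so it crossed groups. Treated arrays correlated with each other at 0.987 to 0.990 and untreated arrays at 0.993 to 0.994.

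miRNAs of the red cell lineage took most of the summed signal, which is probe brightness and does not rank miRNAs by abundance. miR-451, which is processed by Argonaute 2 and is known from maturing erythroblasts, took 59.8% ± 0.78 of the summed signal in controls (SD, n = 2), 54.4% ± 1.77 in untreated SCA (SD, n = 3) and 54.4% ± 1.97 in treated SCA (SD, n = 3). Its share was lower in each SCA group than in controls on every array. The exact two-sided permutation test gave p = 0.1 for each group, the smallest value that 3 against 2 arrays allow. miR-16, a repressor of cell cycle genes, and miR-144, made from the same primary transcript as miR-451, had log2 levels of 5.78 ± 0.08 and 5.39 ± 0.15 in controls (SD, n = 2). All 14 miRNAs of the erythroid list were detected on all 8 arrays. Of the 20 miRNAs listed for other tissues, such as muscle, liver and brain, 0 were detected on any array.

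Treated against untreated SCA addresses which miRNAs of these cells differ under hydroxyurea. Differences are log2 values of treated minus untreated with the standard error of the fit, over 3 and 3 arrays. Here and below, an array counts as higher or lower by its side of the mean of the group it is compared with. miR-373*, the passenger arm of a miRNA known from embryonic stem cells, fell by 0.72 on the log2 scale (SE 0.09, adjusted p = 0.0289) and was lower in 3 of 3 treated arrays. It was detected on 3 of 3 untreated and 2 of 3 treated arrays and on 0 of 2 control arrays. Its value was at the floor on all control and treated arrays, so the floor set the size and the error of this difference. miR-373* was tested only through the untreated arrays, so the filter favoured lower values in the other groups. miR-494, a miRNA of the imprinted 14q32 cluster, differed by -1.18 ± 0.33, from -1.52 ± 0.57 in untreated to -2.70 ± 0.39 in treated SCA (SD, n = 3 each), and missed the threshold (adjusted p = 0.271). The p53-induced miRNAs miR-215 and miR-194 stood at 0.56 ± 0.17 and 0.47 ± 0.17, higher in 3 of 3 treated arrays each, with the same adjusted p. For miR-194 the groups overlapped, with treated replicate 2 (-1.902) just below untreated replicate 1 (-1.892). miR-342-3p, a miRNA of white blood cells, stood at 1.28 ± 0.48.

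Of the 171 miRNAs tested with limma, 1 passed. At an unadjusted p under 0.05 there were 29, where chance alone gives 8.55, with 3 higher and 26 lower in treated SCA. The split between higher and lower followed the scaling: it was 11 and 5 when the percentile was taken over all human probes, 16 and 14 after quantile normalization and 8 and 14 after median scaling. The median of all miRNAs lay at -0.09 and moved to 0.20 with the percentile over all human probes. The groups did not overlap for 26 miRNAs (15.2%), where chance gives 10%. That count was made under the scaling used alone, and a shift shared by many miRNAs can raise it. Among the 20 named miRNAs, miR-149, miR-191*, let-7f-1*, let-7b*, miR-1225-3p, miR-1225-5p, miR-550, miR-1234, miR-1237, miR-33b*, miR-1238 and miR-766 were at -0.46 or lower, each with adjusted p = 0.271. The largest of these was miR-1225-5p at -1.18 ± 0.43, which stood at -0.67 ± 0.16 without treated replicate 3 and at -0.67 and -2.19 in rows 1 and 2. Normexp, whose added offset shrinks differences of dim miRNAs, left it at -0.80, the other 11 of these miRNAs between -0.16 and -0.0279, and miR-373* at -0.0248. miR-30e (-0.22 ± 0.07), miR-140-3p (-0.21 ± 0.07) and let-7a (-0.27 ± 0.10) had smaller differences, which turned positive with the percentile over all human probes (0.09, 0.10 and 0.04).

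**Figure D1:**
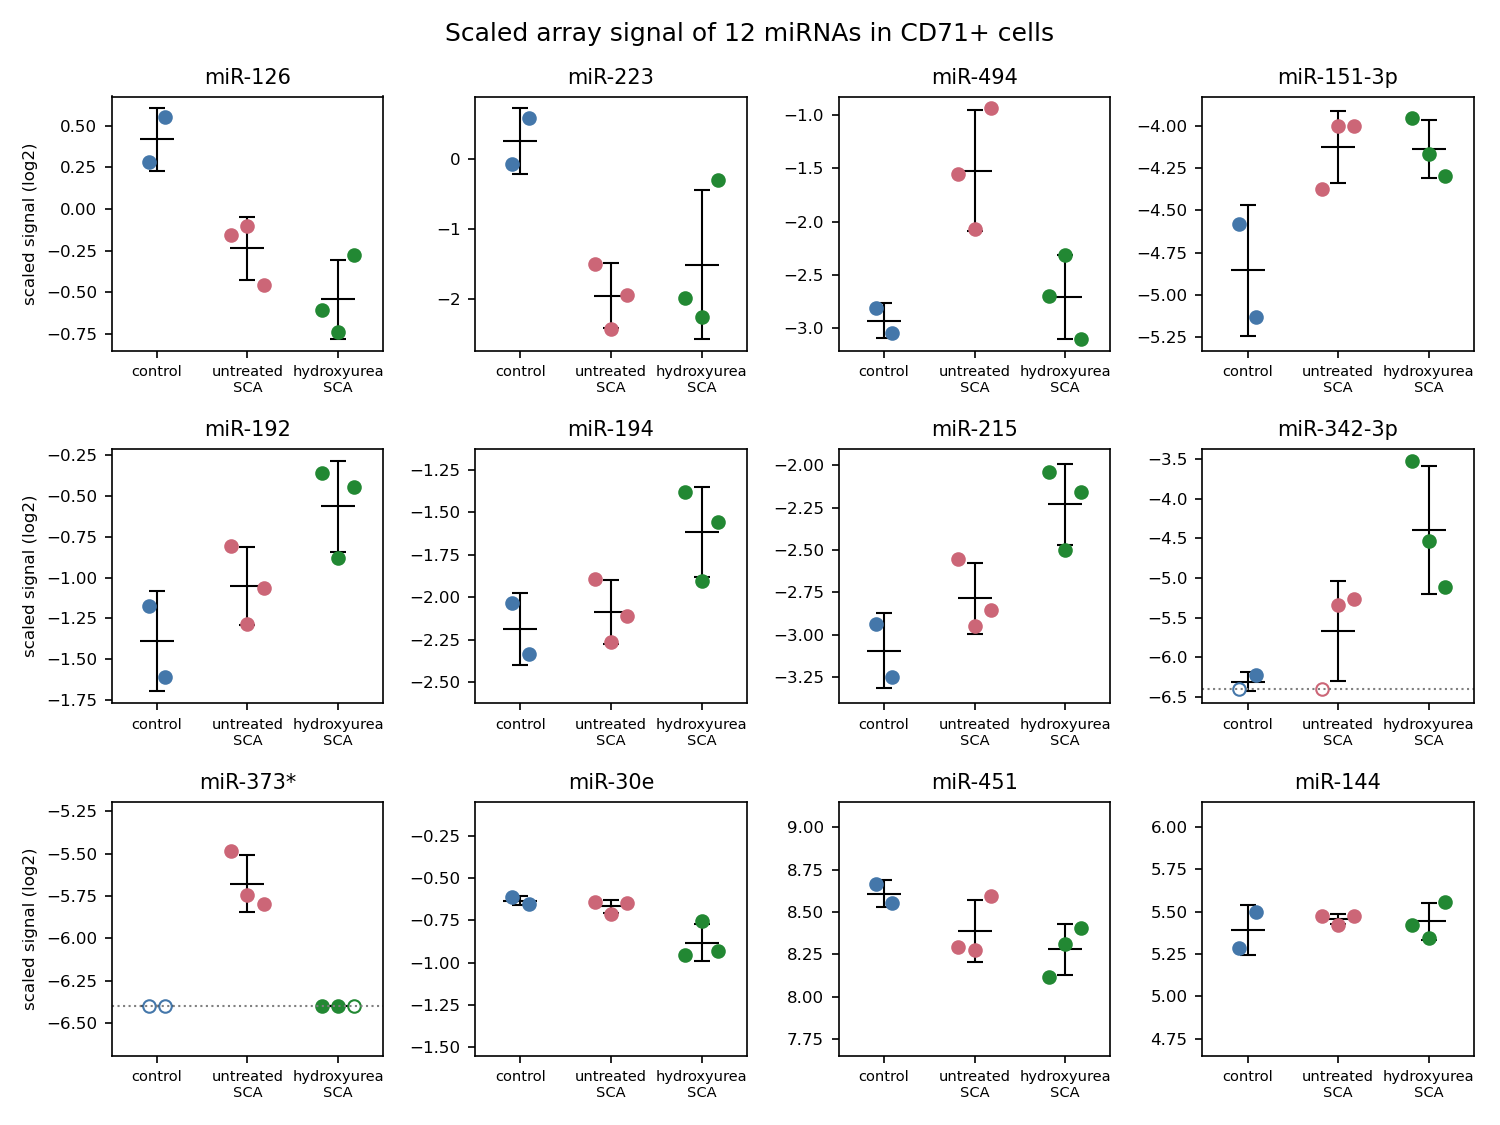
Log2 levels of 12 miRNAs relative to the array's 75th percentile (vertical axis) in the 3 groups (horizontal axis), with 1 point per array, bars for mean ± SD and open points where the miRNA was not detected. The dotted line marks the floor of -6.40, where all control and treated arrays of miR-373* lie. miR-126 and miR-223 are highest in the controls.

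The erythroid miRNAs differed little between the SCA groups. Of the 14 erythroid miRNAs 3 were higher and 11 lower, and 0 passed over all miRNAs or when adjusted over the list alone. miR-16 stood at -0.22 ± 0.09 and miR-107 at -0.21 ± 0.10, and both turned positive with the percentile over all human probes (0.09 and 0.10). miR-451 (-0.11 ± 0.12), miR-144 (-0.01 ± 0.09) and miR-15a (-0.09 ± 0.08) also changed sign with that scaling, while miR-486-5p stayed positive (0.14 ± 0.10). The erythroid plain median of -0.0627 turned to 0.24 with it. Of 12 miRNAs linked to fetal globin 2 were higher and 10 lower, and their plain median of -0.12 turned to 0.19 with all human probes. miR-210, which is also induced by hypoxia, stood at -0.32 ± 0.16 and miR-29b at -0.21 ± 0.12, of which miR-29b turned to 0.10 with all human probes. The let-7 miRNAs, which LIN28 represses, were lower in 8 of 8 tested members, with let-7d at -0.28 ± 0.12 and let-7g at -0.18 ± 0.08. Their plain median moved from -0.20 to 0.11 with all human probes. All 12 tested miRNAs of the miR-17 to miR-92a cluster and its paralogues, which MYC induces, were lower, with miR-20a at -0.17 ± 0.09 and a plain median of -0.08, which moved to 0.22 with all human probes. Neither list had a member past the threshold over all miRNAs or adjusted over the list alone.

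miRNAs linked to stress and to DNA damage were divided. Of 7 tested members of the p53 list 3 were higher and 4 lower. miR-192, miR-194 and miR-215 were the higher ones, the 4 lower ones (miR-16, miR-15a, miR-103 and miR-107) are also on the erythroid list, and the smallest adjusted p over the list alone was 0.0882. Of the 11 hypoxia miRNAs 3 were higher and 8 lower, with miR-181a at -0.50 ± 0.20. The plain medians of the p53 and hypoxia lists turned from -0.0422 and -0.11 to 0.26 and 0.20 with all human probes. The 14q32 list had 3 of 32 members detected, all lower, with miR-134 at -0.97 ± 0.60 and miR-487b at -0.13 ± 0.31, and miR-487b turned positive under each other scaling. Treated replicate 3 carried most of the miR-134 difference: without it miR-134 stood at -0.24 ± 0.13 and the relative median of the list moved from -0.88 to -0.17. miR-134 stood at -0.24 in row 1 and -2.43 in row 2, and at -0.26 with normexp. Adjusted over the list alone, miR-494 passed (adjusted p = 0.0309). Among the 4 hydroxyurea candidates miR-494 passed as well when adjusted over the list alone (adjusted p = 0.0412), and miR-26b (-0.24 ± 0.15), miR-148a (0.09 ± 0.20) and miR-151-3p (-0.01 ± 0.18) did not, of which miR-26b and miR-151-3p turned positive with all human probes. That list may have been chosen on these samples, so the count is not independent evidence. miR-494, miR-134 and miR-1225-5p are also on the list of GC-rich probes prone to background, of which 14 of 15 tested members were lower in treated SCA, at a median of 0.26 below that of all miRNAs (relative median -0.26). That relative median was -0.0805 without treated replicate 3 and -0.0249 with normexp, and the plain median moved from -0.35 to -0.0779 with all human probes.

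Markers of other blood cells were examined beside these groups. Of the 6 myeloid miRNAs 3 were higher and 3 lower, with miR-223, a granulocyte miRNA, at 0.44 ± 0.56 (higher in 1 of 3 treated arrays, and -0.17 without treated replicate 3) and miR-21 at -0.05 ± 0.08, which turned positive under each other scaling. The 5 platelet and megakaryocyte miRNAs were all lower, with miR-130a at -0.55 ± 0.22 and miR-126 at -0.31 ± 0.16. With all human probes miR-126 came to 0.00 and miR-151-3p (-0.01) turned positive. miR-130a stood at -0.22 in row 1 and at -1.22 in row 2, where each SCA group has 1 array. Of the 3 progenitor miRNAs miR-222 stood at 0.17 ± 0.14 and miR-24 at -0.04 ± 0.17, and miR-24 turned positive under each other scaling. miR-150, an abundant lymphocyte miRNA, was not detected on any array. The lymphoid list had 2 tested members, miR-342-3p and miR-181a, too few for a set test. Adjusted over these 2 alone both passed (adjusted p = 0.0458 for each), in opposite directions, and miR-342-3p, which was near the floor, came to 0.0638 with normexp. miR-342-3p was undetected on control replicate 1 and untreated replicate 1. It was tested only through the treated arrays, so the filter favoured its direction. Camera called 0 of the 12 lists (smallest adjusted p = 0.178, and adjusted p = 0.855 with an estimated correlation). Fry called 0 as well, with a smallest adjusted p of 0.323 for movement in 1 direction and 0.349 for change in either. For the hypoxia list the relative median (-0.02) and the direction of camera (up) differed in sign, as they did for the miR-17 to miR-92a list (0.01 and down).

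**Figure D2:**
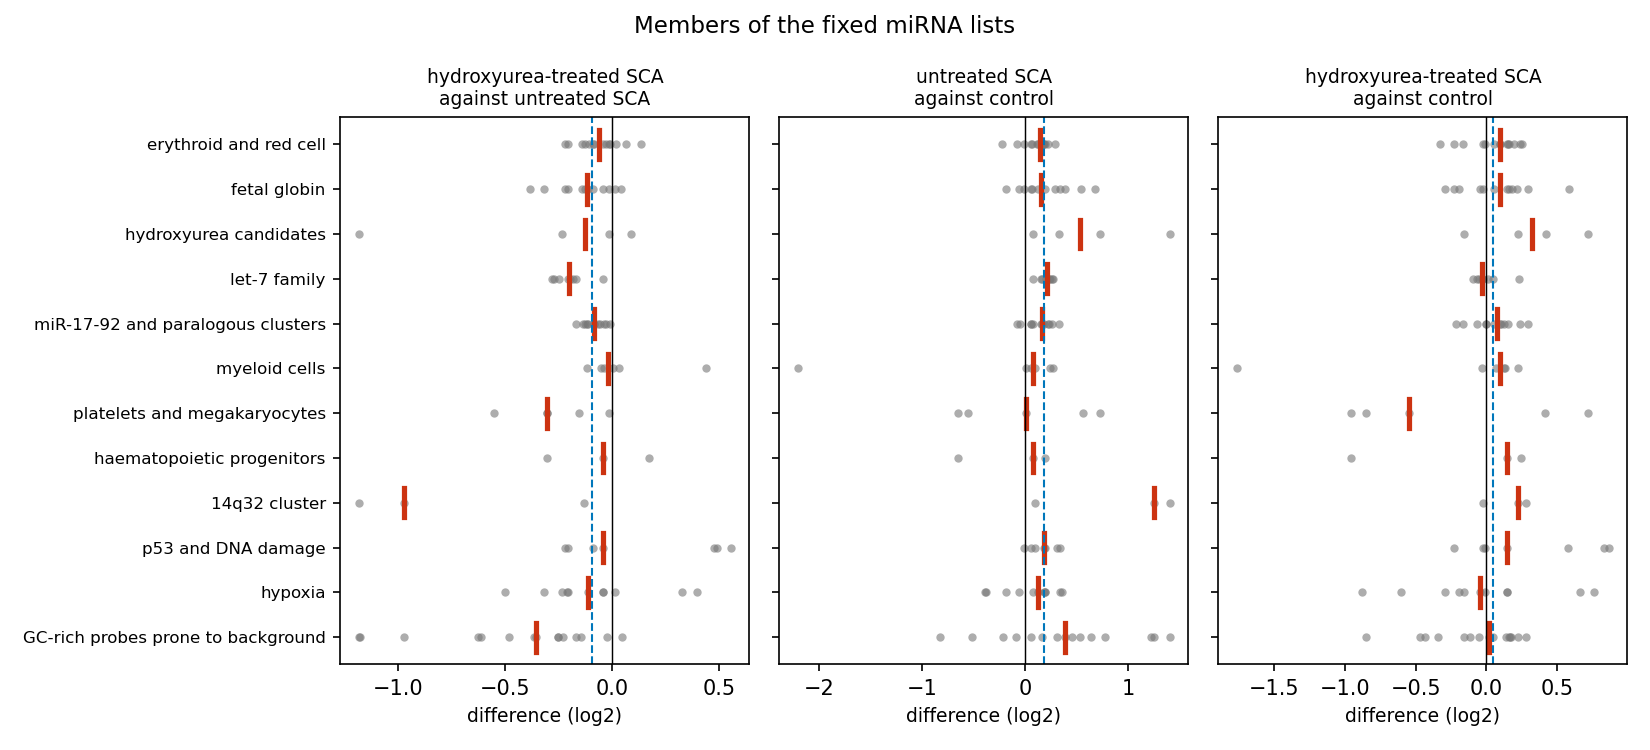
Log2 difference of each tested list member (horizontal axis) by list (vertical axis). Panels show treated minus untreated SCA, untreated SCA minus control and treated SCA minus control. Red bars mark the list medians and blue dashed lines the median of all 171 tested miRNAs. The members of most lists scatter around the blue lines, which lie at -0.09, 0.18 and 0.04 in that order.

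The difference of miR-373* stayed between -0.74 and -0.66 whichever array was left out, but the call was lost in 6 of 8 omissions. The adjusted p of miR-373* was 0.388 and 0.380 without control replicate 1 and 2, 0.170 and 0.227 without untreated replicate 2 and 3, and 0.338 and 0.390 without treated replicate 1 and 3. Without treated replicate 2 the count was 22, all lower and with miR-373* among them, and without untreated replicate 1 it was 1. Over all alternatives the adjusted p of miR-373* ranged from 0.0140 to 0.605, and it was 0.145 with the floor at 0.5 of its value. Row on the slide is balanced over the SCA groups, so the row block left each difference as it was; it gave 0 calls (23 at an unadjusted p under 0.05), with miR-373* at an adjusted p of 0.0796. Within row 1, with 2 arrays against 2, limma called 0 (9 at an unadjusted p under 0.05), and row 2 holds 1 array of each SCA group, which allows no test. The sign of the difference was that of the pooled fit for 140 of 171 miRNAs in row 1, 115 in row 2 and 87 in both. The pooled difference is made from both rows, so agreement with it is partly built in. Only the last count sets 1 row against the other, and the rows shared a sign about as often as not. miR-373* stood at -0.78 and -0.60 in rows 1 and 2, miR-494 at -0.69 and -2.16, miR-215 at 0.48 and 0.70, and miR-342-3p at 1.84 and 0.15. The background-prone list had a median of -0.15 in row 1 and -1.05 in row 2.

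Untreated SCA against control addresses which miRNAs differ with the disease. Differences are untreated minus control over 3 and 2 arrays. miR-223, a regulator of granulocyte development, had the largest difference at -2.21 ± 0.62, or 4.61-fold lower, from 0.26 ± 0.47 in controls to -1.95 ± 0.46 in untreated SCA (SD). miR-126, a miRNA of endothelium, platelets and progenitors encoded within EGFL7, stood at -0.65 ± 0.18. miR-494 was higher by 1.41 ± 0.37 and miR-151-3p by 0.73 ± 0.21. The miR-29 miRNAs, which repress collagen and DNA methyltransferase genes, were higher, with miR-29a at 0.54 ± 0.15, miR-29b at 0.39 ± 0.14 and miR-29c* at 0.51 ± 0.15. These miRNAs moved in the stated direction on 3 of 3 untreated arrays and missed the threshold, with adjusted p = 0.276 for miR-29b and adjusted p = 0.216 for the others. miR-29b turned to -0.0300 with the series table, and normexp left miR-29a at 0.21, miR-29c* at 0.0228 and miR-151-3p at 0.13. miR-373* was the nearest to it (adjusted p = 0.0547). It was detected on 0 of 2 control arrays and was at the floor on both, so the floor set the size and the error of its difference (0.72, against 1.72 with the lower floor and 0.0248 with normexp). miR-149, also undetected in controls, differed by 0.46 ± 0.16 (adjusted p = 0.276) and by 0.0279 with normexp.

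Limma called 0 of 171 miRNAs, and 24 had an unadjusted p under 0.05, where chance gives 8.55, with 20 higher and 4 lower. The split was 4 and 5 with the percentile over all human probes, 7 and 11 after quantile normalization and 7 and 13 after median scaling, and the median of all miRNAs moved from 0.18 to -0.03 with all human probes. The directions of the miRNAs named so far in this comparison were the same under each of these scalings. Groups did not overlap for 66 miRNAs (38.6%), where chance gives 20%. This count was made under the scaling used alone, where the median of all miRNAs was 0.18, and such a shared shift can raise it. Of the other named miRNAs, miR-625 (0.66 ± 0.15), miR-374a (0.33 ± 0.08), miR-148b (0.47 ± 0.12), miR-135a* (0.85 ± 0.29), miR-150* (0.64 ± 0.23), miR-151-5p (0.57 ± 0.21) and miR-130b (0.53 ± 0.20) were higher. miR-21, miR-374b and miR-18b were higher by 0.26 to 0.36, and miR-671-5p was lower at -0.83 ± 0.24. None of them passed, with adjusted p between 0.216 and 0.314. Normexp left miR-135a* at 0.0192, miR-150* at 0.0329 and miR-671-5p at -0.0165, and the other 8 between 0.16 and 0.41, while all human probes left miR-21 at 0.0135 and miR-18b at 0.00779.

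By list, 11 of 14 erythroid miRNAs were higher and 3 lower, with miR-25 at 0.22 ± 0.11 and miR-451 at -0.22 ± 0.14, and their plain median of 0.14 turned to -0.12 with all human probes. Of 12 fetal globin miRNAs 9 were higher and 3 lower, led by the miR-29 miRNAs, while miR-16 (-0.01 ± 0.10), miR-15a (0.06 ± 0.09) and miR-144 (0.06 ± 0.10) lay near 0. All 8 let-7 miRNAs were higher, with miR-98 at 0.28 ± 0.11 and a plain median of 0.22 that turned to -0.04 with all human probes. Of the 12 miRNAs of the miR-17 to miR-92a list 10 were higher and 2 lower, with miR-18a at 0.33 ± 0.16 and a plain median of 0.16 that turned to -0.10 with all human probes. Of 7 p53 miRNAs 6 were higher, with miR-215 at 0.31 ± 0.19, and of 11 hypoxia miRNAs 7 were higher and 4 lower, with miR-26a at -0.39 ± 0.22. With all human probes the plain medians of the fetal globin, p53 and hypoxia lists turned from 0.16, 0.19 and 0.12 to -0.0988, -0.0699 and -0.13. No member of these lists passed when adjusted over the list alone. All 3 detected 14q32 miRNAs were higher, with miR-134 at 1.25 ± 0.67, and miR-494 passed when adjusted over the list alone (adjusted p = 0.0233). All 4 hydroxyurea candidates were higher, although miR-26b (0.08) turned negative with all human probes. miR-494 and miR-151-3p passed when adjusted over the list alone (adjusted p = 0.0230 for each), which is not independent evidence for the reason given above. The background-prone list, which holds miR-494, miR-134 and miR-671-5p, had 11 of 15 members higher and 4 lower, at a relative median of 0.20.

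Markers of other cells went both ways. Of 6 myeloid miRNAs miR-223 alone was lower and 5 were higher, with miR-21 at 0.27 ± 0.09, and 0 passed when adjusted over the list alone (smallest adjusted p = 0.0632). The plain median of the myeloid list (0.08) turned negative with all human probes, as for several lists above, and miR-21 came near 0. Of the 5 platelet and megakaryocyte miRNAs 3 were higher and 2 lower. miR-126 and miR-151-3p passed when adjusted over the list alone (adjusted p = 0.0288 for each), in opposite directions. Of the 3 progenitor miRNAs miR-126 passed in the same way (adjusted p = 0.0298), with miR-24 at 0.19 ± 0.19, which turned negative under each other scaling, and miR-222 at 0.07 ± 0.16. The lymphoid miR-181a stood at -0.38 ± 0.23, and neither lymphoid miRNA passed when adjusted over both alone (adjusted p = 0.274). Camera called 0 of the 12 lists (smallest adjusted p = 0.247, and adjusted p = 0.933 with an estimated correlation), and fry called 0 (0.281 for 1 direction and 0.172 for either). Relative medians and camera's direction differed in sign for fetal globin and the miR-17 to miR-92a list (-0.03 and -0.02, both up).

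Row 2 of the slide held both controls and 1 array of each SCA group. With row as a block limma called 0 (13 at an unadjusted p under 0.05), and miR-223 stood at -1.59 ± 0.63, miR-126 at -0.63 ± 0.23, miR-151-3p at 0.71 ± 0.27 and miR-29a at 0.49 ± 0.18. Within row 2, 1 untreated array against 2 controls gave -2.19, -0.87, 0.85 and 0.61 for the same miRNAs and 1.99 for miR-494. There 144 of 171 differences had the sign of the pooled fit, which contains these arrays, so this agreement is partly built in. The 14q32 list had a plain median of 1.25 in the pooled fit, 0.50 with the block and 1.23 within row 2. Without control replicate 1, which leaves 1 control array assumed to vary like the other groups, the count was 1, a miRNA outside the naming rule that was chosen after its values were seen (miR-574-5p at -2.03, adjusted p = 0.000671). Without untreated replicate 1 it was 1 (miR-373*, adjusted p = 0.0278, in a range of 0.0189 to 0.864) and without treated replicate 3 it was 1 (miR-134, adjusted p = 0.0368, in a range of 0.0177 to 0.890). A fit of only these groups called 3 (miR-134, miR-150* and miR-1225-5p), all on the background-prone list. The brightest probe called 2 (miR-373* and miR-671-5p) and the lower floor 1 (miR-373*). With the brightest probe miR-671-5p differed from control by the same -0.69 in untreated and in treated SCA. Values set to the floor would give that, so the floor may have set its brightest-probe calls in each comparison with control.

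**Figure D3:**
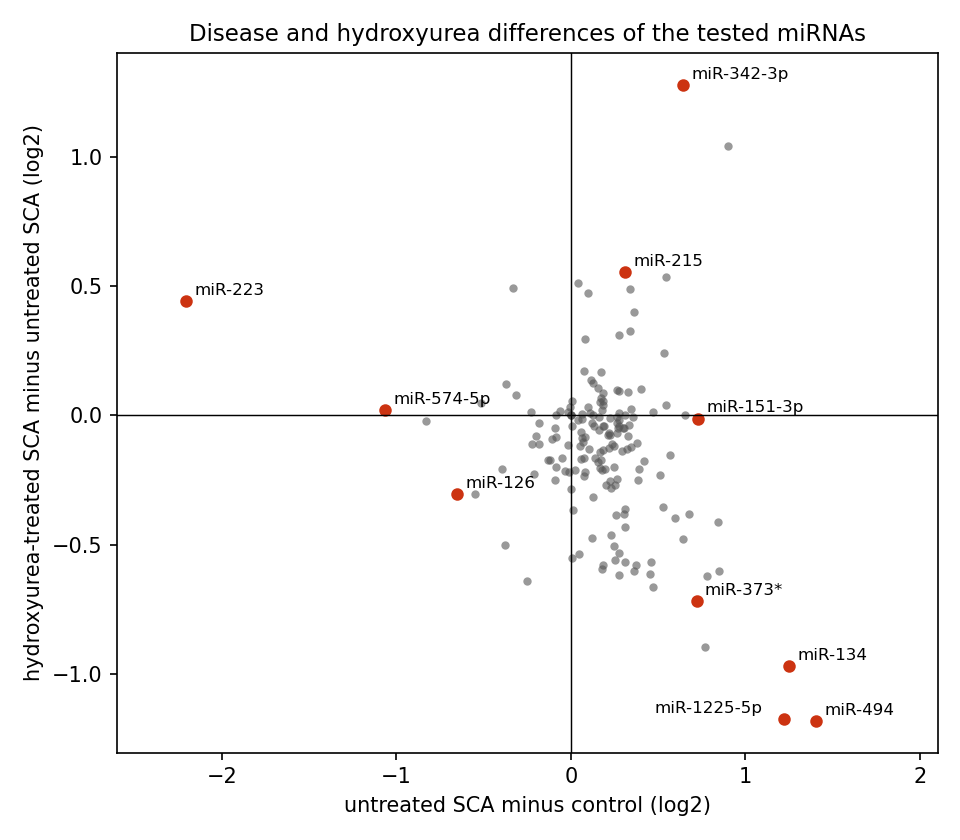
Log2 difference of treated minus untreated SCA (vertical axis) against untreated SCA minus control (horizontal axis) for the 171 tested miRNAs, 1 point each. The correlation across miRNAs was -0.27, against a simulated mean of -0.44 for unchanged groups that share the untreated arrays.

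Treated SCA against control shows how far the treated cells differed from controls. miR-126 stood at -0.96 ± 0.18, or 1.94-fold lower, in 3 of 3 treated arrays (adjusted p = 0.170), and its passenger arm miR-126* at -0.85 ± 0.22. miR-223 was lower as well (-1.76 ± 0.62, adjusted p = 0.253). miR-215 (0.87 ± 0.19) and miR-192 (0.83 ± 0.23), induced by p53, were higher in 3 of 3 treated arrays, with adjusted p = 0.170 and 0.178. miR-342-3p was higher by 1.92 ± 0.53, miR-151-3p by 0.72 ± 0.21, miR-130b by 0.78 ± 0.20, miR-625 by 0.66 ± 0.15, miR-29a by 0.59 ± 0.15 and miR-148b by 0.48 ± 0.12. miR-181a was lower at -0.88 ± 0.23, and miR-494, which differed between the SCA groups by the values above, stood at 0.22 ± 0.37 against control. Each of these directions was the same under all 3 other scalings. Normexp left miR-126 at -0.85, miR-223 at -1.44, miR-192 at 0.64, miR-181a at -0.59, miR-215 at 0.39 and miR-130b at 0.23, but miR-342-3p at 0.12, miR-29a at 0.11, miR-625 at 0.10, miR-148b at 0.0511, miR-494 at 0.00773 and miR-126* at -0.00835, and it turned miR-151-3p to -0.00599.

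Limma called 0 of 171, and 25 had an unadjusted p under 0.05 (15 higher and 10 lower, where chance gives 8.55 in all). The split was 10 and 4 with the percentile over all human probes, 19 and 17 after quantile normalization and 18 and 19 after median scaling. Groups did not overlap for 63 miRNAs (36.8%), where chance gives 20%, counted under the scaling used alone. Adjusted over the list alone, with no correction over lists or comparisons, 3 of 5 platelet miRNAs passed. They were miR-126 (adjusted p = 0.00757), miR-126* (0.0193) and miR-151-3p (0.0208), the last of them higher. miR-126 passed among the 3 progenitor miRNAs (0.00454), and miR-215 (0.0242) and miR-192 (0.0344) among the 7 p53 miRNAs, of which 4 were higher and 3 lower. miR-151-3p passed among the 4 hydroxyurea candidates (0.0499), with the same reservation as before. The 2 lymphoid miRNAs passed in opposite directions (adjusted p = 0.0106 for each), miR-181a lower and miR-342-3p higher. miR-342-3p was tested only because it was detected on every treated array, so the filter favoured its direction. No member of the other lists with a set test passed. The erythroid list had 9 higher and 5 lower, with miR-451 at -0.33 ± 0.14 and miR-486-5p at 0.25 ± 0.11, and the fetal globin list 7 higher and 5 lower. The let-7 family had 3 higher and 5 lower, the miR-17 to miR-92a list 7 and 5, the hypoxia list 4 and 7, the myeloid list 4 and 2, the 14q32 list 2 and 1, and the background-prone list 8 and 7. With all human probes the plain medians of the let-7, hypoxia and background-prone lists turned from -0.0309, -0.0461 and 0.0209 to 0.0195, 0.00430 and -0.00253. Camera called 0 of the 12 lists (smallest adjusted p = 0.685, and adjusted p = 0.948 with an estimated correlation), and fry called 0 (0.234 for 1 direction and 0.0774 for either). For the progenitor list the relative median (0.10) and camera's direction (down) differed in sign.

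With row as a block limma called 0 (13 at an unadjusted p under 0.05), with miR-126 at -0.94 ± 0.23, miR-215 at 0.87 ± 0.25 and miR-223 at -1.15 ± 0.63. Within row 2, 1 treated array against 2 controls gave -0.70, 0.94 and -0.55 for them. There 140 of 171 differences had the sign of the pooled fit, which contains these arrays as well. The background-prone list had a plain median of 0.02, which was -0.31 with the block and -0.53 within row 2. A trended robust prior called 1 (miR-126, adjusted p = 0.0358, the lowest of its alternatives, which reached 0.587), the brightest probe 1 (miR-671-5p), and leaving out control replicate 1 gave 1 (miR-574-5p).

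All SCA against control pools both SCA groups, 6 arrays against 2. miR-126 stood at -0.81 ± 0.16 (adjusted p = 0.160), miR-223 at -1.99 ± 0.56 (adjusted p = 0.175) and miR-151-3p at 0.72 ± 0.18 (adjusted p = 0.170), each in that direction in 6 of 6 SCA arrays. miR-29a stood at 0.56 ± 0.13 and miR-671-5p at -0.84 ± 0.22. Normexp left miR-126 at -0.71 and miR-223 at -1.61, but miR-151-3p at 0.0632, miR-29a at 0.16, miR-671-5p at -0.0313 and miR-126* at -0.00448. Limma called 0 of 171, and 26 had an unadjusted p under 0.05 (18 higher and 8 lower). The split was 3 and 5 with all human probes, 12 and 15 after quantile normalization and 12 and 17 after median scaling. Groups did not overlap for 26 miRNAs (15.2%), where chance gives 7.14%, counted under the scaling used alone. Quantile normalization gave 4 calls (miR-126, miR-148b, miR-625 and miR-671-5p), median scaling 2 (miR-652 and miR-671-5p), the gene-level signal 1 (miR-29a) and the brightest probe 1 (miR-671-5p). The call with the brightest probe carries the reservation about the floor given above. miR-652 lies outside the naming rule. Without control replicate 1 the count was 1 (miR-574-5p) and without treated replicate 3 it was 1 (miR-134). With row as a block it was 0 (13 at an unadjusted p under 0.05). Adjusted over the list alone, with no correction over lists or comparisons, miR-126 (adjusted p = 0.0105), miR-151-3p (0.0181) and miR-126* (0.0188) passed among platelet miRNAs. miR-126 also passed among progenitor miRNAs (0.00627) and miR-151-3p among the candidates (0.0290). The lymphoid miR-181a (lower) and miR-342-3p (higher) passed among those 2 (0.0350 for each), where miR-342-3p was tested only through the treated arrays. Camera called 0 of the 12 lists (smallest adjusted p = 0.568, and adjusted p = 0.950 with an estimated correlation), and fry called 0 (0.343 for 1 direction and 0.144 for either). Of the erythroid list 11 were higher and 3 lower, of the p53 list 6 and 1, and of the myeloid list 4 and 2. The erythroid plain median of 0.13 turned to -0.00656 with median scaling. Relative medians and camera's direction differed in sign for the erythroid (0.01, down), progenitor (0.04, down), background-prone (0.03, down), fetal globin and let-7 lists (-0.04 for let-7, both up).

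An F test over the 3 groups called 1 miRNA, miR-373* (adjusted p = 0.0479), with 25 at an unadjusted p under 0.05. The row block gave 0 (9 at an unadjusted p under 0.05), and leaving out 5 of the 8 arrays in turn, namely control replicate 2, untreated replicates 2 and 3 and treated replicates 1 and 3, gave 0. Without control replicate 1 it was 1 (miR-574-5p), and without treated replicate 2 it was 9.

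The 3 groups also allow the question whether the hydroxyurea difference opposes the disease difference. Across the 171 miRNAs, which are not independent replicates, the treated-untreated difference correlated with the untreated-control difference at -0.27. Both differences contain the untreated arrays with opposite signs. Simulated unchanged groups sharing them gave a mean of -0.44 (95% of simulations between -0.63 and -0.21). The covariance was -0.0325 against a simulated -0.0257. Signs were opposite for 64.9% of miRNAs against a simulated 64.7%. None of these values lay beyond the simulated range. The 3 untreated arrays were too few to split into parts of 2. Without treated replicate 3 the correlation was -0.11, and with row as a block it was -0.17.

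Probe targets lay on hg18 as follows. The erythroid pair miR-451 (chromosome 17, 24212530 to 24212550) and miR-144 (24212729 to 24212747) are neighbours. miR-373* lies on chromosome 19 (58983786 to 58983797) beside MIR371A, MIR371B and MIR372, outside any annotated host gene. miR-494 lies on chromosome 14 (100565779 to 100565792) among miRNA genes of the 14q32 cluster, and miR-342-3p on the same chromosome (99645813 to 99645827) within EVL. miR-126 lies on chromosome 9 (138684931 to 138684947) within EGFL7, and miR-223 on chromosome X (65155506 to 65155525) within MIR223HG. miR-215 (chromosome 1, 218357845 to 218357864) lies within IARS2 next to MIR194-1 (218358142 to 218358157), and miR-192 (chromosome 11, 64415211 to 64415228) within MIR194-2HG next to MIR194-2 (64415423 to 64415438). miR-151-3p lies on chromosome 8 (141811895 to 141811911) within PTK2, miR-29a on chromosome 7 (130212090 to 130212108) next to MIR29B1, and miR-149 on chromosome 2 (241044111 to 241044127) within GPC1. Whether these targets are exonic or intronic was not analysed here.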

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

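The tests of the slide row and of leaving out treated replicate 3 were set before their results were seen; the tests of scaling, brightness, platelets, myeloid cells, cross-hybridization and other splits were chosen only after the result was seen. For miR-223 and miR-126, a test of residual lymphocytes was run first (miR-150 was detected on 0 of 2 control arrays, which argued against them), and the test of myeloid cells then took its place because miR-223 is a myeloid miRNA. Probes for viral miRNAs, which enter no comparison, were detected more often in SCA than in controls. On average 4.67 of the 76 viral miRNAs were detected per untreated array and 5 per treated array, against 3 per control array (exact permutation p = 0.3 and p = 0.4, where 0.1 is the smallest possible). The treated arrays ranged from 3 to 7, so they overlapped with the controls. Whether these signals come from viral miRNAs, cross-hybridization or background was not tested, and the mean number of human miRNAs detected ran the same way (160.5 in controls, 170 in untreated and 189 in treated SCA).

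Members of the background-prone list were dimmer in treated than in untreated SCA, at a mean of -0.45 ± 0.27, and no explanation below was excluded. Without the scaling, the 10 members detected on all arrays stood at -0.0644 ± 0.27 against -0.49 with it, a shift that all miRNAs share, so it decides nothing about why this list stands apart: against all miRNAs the list was at -0.26, and at -0.27, -0.22 and -0.24 under the other scalings. With array brightness (the same percentile) as a covariate the mean was -0.11 ± 0.26, and without treated replicate 3 the median was -0.16 ± 0.19 against -0.35 with it, both within their errors of 0. The covariate is also the divisor of the scaling, so its slope (-0.80 ± 0.38) and the smaller mean are partly built in. The row block left the median at -0.35 because rows are balanced over the SCA groups, so that value could not have come out otherwise and the bound set for it beforehand decides nothing. A difference brought by hydroxyurea stays open as well, untested, since treatment and brightness cannot be told apart with 3 arrays each.

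miR-223 and miR-126 were dimmer in SCA than in controls, at a mean of -1.40 ± 0.38 for the pair. Slide row as the whole cause is argued against only weakly. The mean was -1.08 ± 0.43 with row as a block, but the pair was picked from these data and both controls share row 2. Within row 2, which holds 1 array of each SCA group, miR-223 stood at -2.19 in untreated and -0.55 in treated SCA against control. miR-126 stood at -0.87 and -0.70 there. More residual platelets in the control preparations stay open: miR-130a stood at -0.27 ± 0.22, above miR-126 by 0.54 ± 0.39, which is within 2 standard errors, while miR-151-3p (0.72 ± 0.18) and miR-151-5p (0.49 ± 0.19) of the same list were higher, against this explanation, but are not restricted to platelets. More residual myeloid cells stay open too, although the CD45 depletion should remove them: miR-142-3p stood at 0.0651 ± 0.0571, which decides nothing, since it is not restricted to myeloid cells and the bound set to exclude them compared the signals of different probes. A difference brought by the disease remains a candidate explanation that the design does not separate from these.

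miR-192, miR-194 and miR-215, which lie in a pair of clusters, were brighter in treated than in untreated SCA. Cross-hybridization between the similar miR-192 and miR-215 alone would not account for miR-194, of another sequence, at 0.47 ± 0.17. That decides little, since miR-194 was singled out for its difference in these data. Whether the probes of miR-192 and miR-215 read each other was not tested. The mean of the 3 was 0.51 ± 0.19 under the scaling used and 0.57 ± 0.22 or higher under each other scaling. This cannot exclude the choice of scaling, because the scaling used gave the lowest median of all miRNAs (-0.09). That median was 0.20 with all human probes, 0 after quantile normalization and 0.02 after median scaling, so each tended to raise differences. The row block left the mean at 0.51 by construction and decides nothing, and the differences of miR-215 and miR-194 were positive within each row (0.48 and 0.70, 0.44 and 0.55). A difference brought by hydroxyurea is a hypothesis that no test here decides, since it needs the same people before and after treatment, and the miRNAs missed the threshold over all miRNAs (adjusted p = 0.271 for miR-194 and miR-215).

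For the count of calls between treated and untreated SCA, 2 of the 10 splits of the 6 SCA arrays gave as many, with 1 call in the real split and 1 as the highest of the others. With 10 splits no share under 0.05 can be reached. At an unadjusted p under 0.05 the real split gave 29 and the highest other split 39. That split parts the 3 SCA arrays with the highest 75th percentile, 2 of them treated, from the other 3, which was noticed after the counts were seen, and whether brightness or chance made it was not tested.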

How the results depend on the processing

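The soft floor, the restriction to miRNAs above the floor on all arrays, the row block of the correlation and camera with an estimated correlation under each other setting were chosen after seeing the data. The rule for calling an uncalled value reversed was also set after seeing the values: it asks for a call or for both values beyond their standard errors. The value of a list, at first its plain median, was likewise set against the median of all tested miRNAs after seeing the values. Counting every change of sign, 186 of 4111 values of named miRNAs changed sign (72 of 173 did so at least once), and 107 of 1240 values of lists (34 of 48). Unless stated, the cause of a change was not tested. A block for slide or scan was not run, since there was 1 of each. Signal over background limits the dim miRNAs: 32 of the 171 tested were at the floor on at least 1 array.

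The count for treated against untreated SCA was 1 and fell to 0 in 21 of 24 alternatives: each of the 3 other scalings, normexp, the gene-level signal, the series table, the lower floor, no filter, the stricter filter, the trended prior, the fit of only these groups, the replicate block, the row block, the soft floor, the floor-free set and 6 of 8 omissions of an array. Leaving out arrays gave 0 to 22, the most without treated replicate 2. The F test count of 1 became 0 in 19 of 23 alternatives and 2 with the brightest probe, and it ranged from 0 to 9 over omitted arrays (9 without treated replicate 2). The count for untreated SCA against control was 0 in 18 of 24 alternatives, 1 with the lower floor, 2 with the brightest probe and 3 with only these groups, and 0 to 1 over omitted arrays (1 without control replicate 1, untreated replicate 1 or treated replicate 3). Treated SCA against control gave 0 in 21 of 24, 1 with the brightest probe or the trended prior, and 0 to 1 over omitted arrays (1 without control replicate 1). All SCA against control gave 0 in 18 of 24, 4 with quantile normalization, 2 with median scaling, 1 with the gene-level signal or the brightest probe, and 0 to 1 over omitted arrays (1 without control replicate 1 or treated replicate 3). With 1 array left in a group, it was assumed to vary like the others.

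The groups hold separate people, so the replicate numbers were not taken as pairs. Over 7 same-numbered pairs the correlation of deviations ran from -0.42 to 0.24, and 3 of them lay over 0.1. Between the SCA groups it was 0.13, -0.08 and -0.42 for replicates 1 to 3. These correlations cannot exclude pairing, since deviations from a mean of 2 or 3 arrays are tied to each other. With the replicate block all 5 counts were 0 (12, 21, 19, 22 and 15 at an unadjusted p under 0.05), and the p53 list passed camera (adjusted p = 0.0401, relative median 0.0489), though not with an estimated correlation (adjusted p = 0.659).

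Lists are given as the list median minus that of all tested miRNAs, treated minus untreated SCA unless named. None passed camera in the reported setting. Each pass below used the preset correlation of 0.01, and with the correlation estimated 0 lists passed in any setting or comparison (smallest adjusted p = 0.0823). The background-prone list passed with all human probes (-0.27), median scaling (-0.24), the gene-level signal (-0.26), the series table (-0.33) and no filter (-0.17), and over omitted arrays it ran from -0.45 to -0.0805, passing without treated replicate 2. The 14q32 list passed with all human probes (-0.86). With normexp the let-7 family (-0.10) and the p53 list (0.0551) passed. Without untreated replicate 2 the let-7 family (-0.10, range over omitted arrays -0.13 to -0.0621) and the myeloid list (0.28, range -0.0803 to 0.28) passed. With no filter the median of all 719 miRNAs is 0 because most lie at the floor, so any detected list stands apart by construction. There the fetal globin (-0.10), candidate (-0.12), hypoxia (-0.0429), myeloid (0), 14q32 (0) and p53 (0) lists passed, and the erythroid (-0.0627) and miR-17 to miR-92a (-0.0843) lists reversed. In untreated SCA against control the erythroid (0.14), fetal globin (0.0944), miR-17 to miR-92a (0.16), myeloid (0.0618) and hypoxia (0.0758) lists reversed in the same way, as did the fetal globin (0.11), let-7 (0.0687) and myeloid (0.0651) lists in all SCA against control. In untreated SCA against control the 14q32 list passed with all human probes (1.03) and the candidate list with the series table (0.34), and further lists passed against control only without a filter.

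The correlation of the disease and hydroxyurea differences was -0.27, -0.17 with row as a block, -0.44 in simulated unchanged groups, and -0.38 to -0.11 over omitted arrays (-0.38 without untreated replicate 3 and -0.11 without treated replicate 3). Among named miRNAs, miR-373* lost its call in 19 alternatives of the treated-untreated comparison. miR-223 and miR-126 kept their direction against control in all 24 alternatives of each comparison with control.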

Other observations

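Most lymphoid and progenitor miRNAs were not detected on all 8 arrays. Of the 6 lymphoid miRNAs miR-150 and miR-146a were detected on no array, and miR-155, which is induced in activated lymphocytes and present in early progenitors, was detected on 1 of 3 treated arrays and on none of the others. Of the 12 progenitor miRNAs, 6 were detected on any array and 2 on all 8. miR-142-3p, a miRNA of all blood lineages, lay at 2.37 ± 0.03 in controls (SD, n = 2), 2.43 ± 0.06 in untreated SCA and 2.43 ± 0.02 in treated SCA (SD, n = 3 each). The 10 brightest miRNAs took 85.7% ± 0.20 of the signal in controls, 83.0% ± 0.78 in untreated SCA and 83.0% ± 1.23 in treated SCA (SD). The first 2 principal components held 34.6% and 26.7% of the variance of the tested miRNAs. On the first, treated replicate 3 (3.66) lay near the controls (2.13 and 3.24). The other treated arrays (-0.59 and -2.96) lay near untreated SCA (-3.19 to -0.59) there. On the second, the treated arrays (-4.38 to -0.86) lay below all others (0.80 to 2.16).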
